A study of Mus musculus with 6 samples.

How the data were processed

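Total RNA of mouse chondrocytes was extracted with TRIzol and made into libraries with a VAHTS Universal V6 kit, per the labels' protocols. Strand, annotation release and filters are not given in the sources used here. The submitters' processing notes name fastp, HISAT2, HTSeq and the genome build GRCm39, without versions or roles. The authors deposited a table of whole-number read counts per gene and a table of FPKM values for 23867 gene symbols, each with 6 columns. Tested on all entries but those with low counts, each deposited FPKM equals the count divided by the column total and by 1 length per gene.

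The wild-type columns matched the sample titles by name and number. The knockout columns, named CRE1 to CRE3, showed their group but not which knockout sample they hold, so they were used as replicates of the group, and the main test pairs nothing. Every pair of libraries within a group differed by more than sampling noise, with a chi-square of 3.19 to 8.09 per degree of freedom. The libraries were therefore counted separately. Separate preparations of a shared pool can also exceed sampling noise, so this does not show that the libraries are independent replicates. Column totals were 31481779 to 37814723 in the knockout and 39267487 to 40152687 in the wild type. The biological coefficient of variation was 4.88%.

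Counts were compared with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood test, two-sided, design with the group alone, TMM factors, filterByExpr with a minimum count of 10), which kept 15028 genes. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. The SE of a log2 fold change is its size divided by the square root of the F statistic. Gene lists were tested with camera in limma 3.58.1 on log2 CPM, with a preset correlation of 0.01 and adjustment over 36 lists as a family, of which 23 were pathways and 13 were markers of cell types or states. The lists, the rule for the genes named and the other settings to be tried were fixed before the data were examined. The lists were mitochondrial fusion and fission, contacts of endoplasmic reticulum and mitochondria, integrated stress response, endoplasmic reticulum chaperones, mitochondrial chaperones, nuclear-encoded and mitochondrially encoded respiratory subunits, mitochondrial biogenesis, cartilage, hypertrophy, proteases, protease inhibitors, inflammatory mediators, interferon response, NRF2, glycolysis and hypoxia, fatty acid oxidation, lipid synthesis, apoptosis, proliferation, autophagy, TGF-beta and WNT signalling. The marker lists covered fibroblasts, osteoblasts, macrophages, neutrophils and lymphocytes, endothelium, pericytes, skeletal muscle, erythroid cells, adipocytes, nerve, keratinocytes, dissociation response and sex-linked genes.

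The genes named were Mfn2, the 10 largest rises and the 10 largest falls among called genes with separated groups and a mean log2 CPM of at least 1, the 3 members of each gene list with the smallest p, and 1 member per marker list, with all 5 sex-linked genes. Predicted genes, genes without a symbol and sex-linked genes were left out of the largest changes. Some genes that this rule takes are not reported here. For 25 list symbols an older or a RefSeq name was matched to the table.

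The other settings were DESeq2 1.42.0, limma-voom, DESeq2's size factors, upper-quartile factors, no filter on low counts, a CPM above 1 in 3 libraries, a test against a 1.2-fold change, each library left out in turn, limma on log2(FPKM + 1) and log2(FPKM + 0.1) of genes with a mean FPKM of at least 1 and without that filter, camera with an estimated correlation, and fry. Total counts without TMM, removal of the 20 most abundant genes, removal of a smooth trend on gene length and transcript GC content, and a block on the number at the end of each column name were added after seeing the data. Length and GC content were available for 93.5% of the tested genes. Transcript GC content came from an annotation of the preceding mouse assembly, so no coordinates are given. The counts of calls were also taken over the 10 splits of the 6 libraries into groups of 3.

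The test was checked on simulated counts with the means and library sizes of these libraries, over 14859 genes in the knockout against wild type comparison. It recovered 82% of genes changed 1.5-fold, 86% of those changed 2-fold and 98% of those changed 4-fold, and 6.51% of its calls were unchanged genes. In the simulation 50 genes were changed at each fold, with as many rises as falls, and all other means were equal between the groups. In the data 62.7% of the tested genes were called. The check therefore does not cover scaling or error rates where most genes change. Genes with near-identical copies, such as Saa1 and Saa2, Ifit3 and Ifit3b, or Hspa1a and Hspa1b, and overlapping or antisense genes have uncertain separate counts.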

Results

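Transcripts of mouse chondrocytes, the cells that make and maintain cartilage, were measured by bulk RNA sequencing in 6 libraries. Of these, 3 came from wild-type mice and 3 from mice whose label pairs a knockout of Mfn2 with Col2a1, a cartilage collagen gene. Mfn2 encodes mitofusin 2, a protein of the mitochondrial outer membrane that fuses mitochondria and also sits at their contacts with the endoplasmic reticulum. The title of the series places the comparison within work on crosstalk between mitochondria and endoplasmic reticulum in osteoarthritis. The knockout libraries are called CRE1, CRE2 and CRE3 and held 31481779 to 37814723 counts, and the wild-type libraries held 39267487 to 40152687. Values after ± are SDs over n = 3 libraries, levels are TMM-normalized CPM (counts scaled to a common library size), and fold changes are knockout against wild type with the standard error (SE) of the log2 value. The labels do not say whether the libraries of a group came from separate animals, pools or cultures, so the p-values measure only the spread between these libraries.

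The targeted gene was lower in each knockout library than in any wild-type library. Mfn2 stood at 60.0 ± 3.78 CPM in the knockout and 107 ± 0.937 CPM in the wild type, with 64.0, 56.5 and 59.4 CPM in CRE1, CRE2 and CRE3 against 106 to 108 CPM in the wild-type libraries. Its log2 fold change was −0.84 (SE 0.046, adjusted p = 2.24e-10, edgeR quasi-likelihood test), a level 0.559 times that of the wild type. The count covers the whole gene and does not resolve which exons were deleted. It also does not separate cells that carry the deletion from other cells, or a change in the mix of cells. For scale, 1803 genes were lowered at least 2-fold, more than Mfn2 was.

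The transcriptome differed broadly between the groups. Among the 10 largest rises were the acute-phase genes Saa2 (log2 fold change 6.90, SE 0.080) and Saa1 (5.87, SE 0.048), the inducible nitric oxide synthase Nos2 (6.52, SE 0.066), the cytokine Il6 (5.17, SE 0.121) and the prostaglandin synthase Ptgs2 (4.82, SE 0.060). Nos2 went from 5.35 ± 0.832 to 492 ± 10.7 CPM, a 92.0-fold rise, and Il6 from 1.11 ± 0.351 to 40.3 ± 1.41 CPM. Il13ra2 (5.62), Rab33a (5.22), Serpinb2 (5.00), Ascl2 (4.99) and Rtn4rl2 (4.97) completed the group. Saa1 and Saa2 are near-identical copies whose reads can be exchanged, so their separate values are uncertain. Among the 10 largest falls were Fcrl2 (−7.21, SE 0.129), Cd5l (−6.89), Cd72 (−6.59), Hpgds (−6.43), Clec12a (−6.25), Stap1 (−6.14), the complement genes C1qc (−5.96) and C1qb (−5.70) and Cd300lb (−5.64). Fcrl2 fell from 33.4 ± 1.01 to 0.220 ± 0.030 CPM, a 148-fold difference. C1qc and C1qb are on the macrophage marker list, which fell as a set (median log2 fold change −4.05). These falls therefore need not be changes within chondrocytes, and the cell source of the falling genes was not tested. The largest adjusted p among these 20 genes was 2.52e-11, for Rtn4rl2.

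Of 15028 genes tested, 9430 changed (62.7%) at a Benjamini-Hochberg adjusted p under 0.05 in edgeR's quasi-likelihood test, 4607 upward and 4823 downward. Of these, 2965 changed at least 2-fold, 1162 upward and 1803 downward. In 67.1% of the tested genes the 3 knockout libraries lay wholly above or below the 3 wild-type libraries, where chance gives 10%. The 20 most abundant genes took 17.8% ± 0.287 of the counts in the knockout and 13.1% ± 0.185 in the wild type. Log2 CPM correlated across genes, which are not independent replicates, at 0.989 to 0.994 within a group and at 0.922 to 0.924 between groups. The split between rises and falls depended on the scaling: 48.9% of the calls were rises with TMM factors, 38% with upper-quartile factors and 26.8% with total counts alone. A limma fit on log2(FPKM + 1), which also changed the test, the transform and the filter, gave 28.1%. With total counts alone the median log2 fold change of all genes moved by −0.209, so changes of about that size or less are read relative to that shift.

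Genes of cytokines and inflammatory mediators rose together. Of 29 tested members, 25 rose and 4 fell, with a median log2 fold change of 1.86 (camera adjusted p = 2.79e-09, and adjusted p = 0.0298 with an estimated correlation). Saa3 rose 16.8-fold, from 882 ± 19.1 to 14839 ± 528 CPM (log2 fold change 4.07, SE 0.029). Lcn2, a siderophore-binding protein, rose 8.67-fold and Cxcl5, a chemokine that attracts neutrophils, rose 6.77-fold. The members that fell were Tnf (−3.50), Vcam1 (−0.57), Csf1 (−0.27) and Icam1 (−0.15), named after their values were seen. Markers of macrophages fell over the same libraries (list median −4.05), and the immediate-early and dissociation-response list had a median of 0.78.

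Matrix-degrading proteases went both ways, with the stromelysin Mmp3 and the collagenase Mmp13 at the top. Mmp3 rose 22.9-fold, from 898 ± 5.05 to 20526 ± 435 CPM (log2 fold change 4.51, SE 0.023), and Mmp13 rose 10.8-fold, from 339 ± 4.84 to 3674 ± 72.7 CPM (3.44, SE 0.026). Ctss, a cathepsin also made by macrophages, fell 12.6-fold. In the list of 27 tested proteases, 13 rose and 8 fell (camera adjusted p = 0.480; over the other settings 11 to 14 rises and 7 to 14 falls). Among 10 inhibitors of proteases, 4 rose and 4 fell (adjusted p = 0.571). Timp1 rose 3.37-fold, while Timp3 fell from 7434 ± 72.0 to 3916 ± 89.0 CPM.

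**Figure D1:**
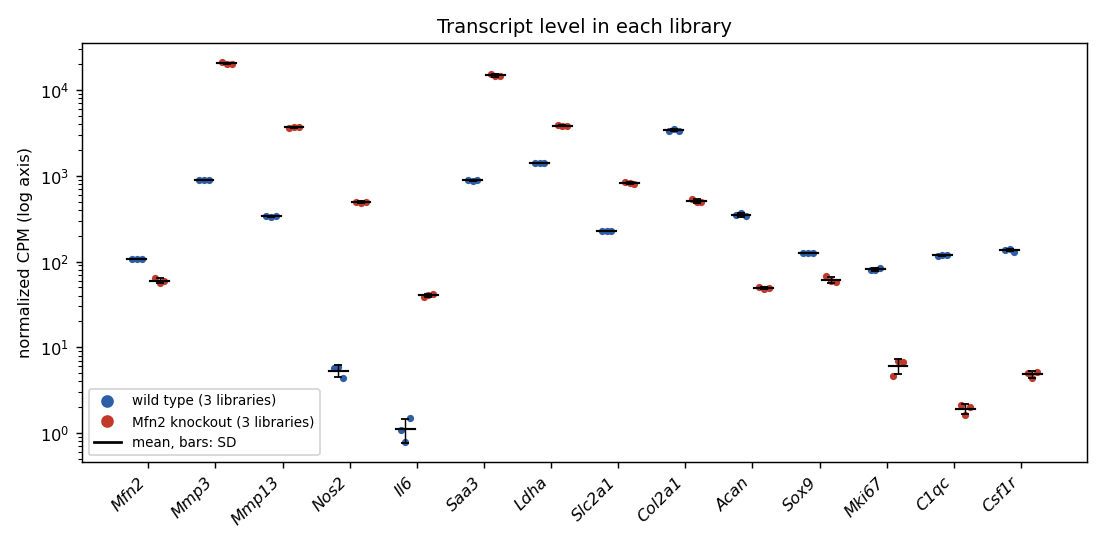
TMM-normalized CPM of 14 genes on a log axis, with 1 point per library, the mean as a line and the SD as a bar, wild type in blue and knockout in red (3 libraries each). Mfn2 lay at 60.0 CPM in the knockout and 107 CPM in the wild type, Mmp3 and Nos2 were higher in the knockout, and Col2a1 and C1qc were lower.

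Genes of cartilage matrix and chondrocyte identity fell. Of 28 tested members, 21 fell and 4 rose, with a median log2 fold change of −0.998 (camera adjusted p = 5.67e-05, but adjusted p = 0.0657 with an estimated correlation). Col2a1, the main cartilage collagen, fell from 3397 ± 71.3 to 509 ± 29.0 CPM (log2 fold change −2.74, SE 0.036). The proteoglycan Acan fell from 352 ± 17.9 to 49.0 ± 1.55 CPM (−2.85, SE 0.044) and Ucma, a secreted cartilage matrix protein, fell 4.99-fold. Prg4, which encodes the joint lubricant lubricin, rose instead (1.64), as did Matn1 (1.30), Snorc (0.49) and Sox5 (0.21), all named after their values were seen. Adjusted over the list alone, 22 members fell and 4 rose. Macrophage markers fell over the same libraries (list median −4.05), the immediate-early list had a median of 0.78, and fibroblast markers went both ways.

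Of 20 tested genes of chondrocyte hypertrophy and mineralization, 9 rose and 8 fell, and camera did not call the list against other genes (adjusted p = 0.546; over the other settings 8 to 10 rises and 5 to 9 falls). Besides Mmp13, the rises included the bone matrix protein Spp1 (log2 fold change 2.26, SE 0.039) and the angiogenic factor Vegfa (1.64, SE 0.029). The largest fall in this list was that of Ibsp (−3.63), which is also on the osteoblast list. In the osteoblast and osteocyte list, 2 of 8 tested members rose and 6 fell (adjusted p = 0.0858; over the other settings 1 to 2 rises and 1 to 6 falls), and Ibsp, a bone sialoprotein, fell 12.4-fold.

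All 26 genes of glycolysis and the hypoxia response rose. Their median log2 fold change was 1.23 (camera adjusted p = 2.11e-13, but adjusted p = 0.212 with an estimated correlation). The lactate exporter Slc16a3 rose 3.87-fold, the glucose transporter Slc2a1 rose 3.62-fold, from 227 ± 1.19 to 823 ± 14.4 CPM, and the lactate dehydrogenase Ldha rose 2.71-fold, from 1417 ± 6.03 to 3841 ± 47.7 CPM. Over the same libraries macrophage markers fell (list median −4.05), and the immediate-early and dissociation-response list had a median of 0.78 (adjusted p = 0.0263, but adjusted p = 0.218 with an estimated correlation).

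Genes of mitochondrial fusion, fission and mitophagy split, with 8 of 21 tested members higher and 6 lower (camera adjusted p = 0.622; over the other settings 3 to 9 rises and 3 to 11 falls). The mitophagy receptors Bnip3 (log2 fold change 1.54, SE 0.027) and Bnip3l (1.44, SE 0.030) rose, and both are also known targets of hypoxia signalling. In the list for contacts between endoplasmic reticulum and mitochondria and for calcium transfer, 12 of 31 members rose and 9 fell (adjusted p = 0.501), and over the other settings the list gave 10 to 13 rises and 3 to 18 falls, with more falls than rises with total counts alone. Ero1a, an oxidase of the endoplasmic reticulum, rose 3.77-fold and the outer-membrane channel Vdac1 rose 2.68-fold. Mitochondrial chaperones and proteases rose in 6 of 14 cases and fell in 3 (adjusted p = 0.480; over the other settings 4 to 8 rises and 0 to 7 falls), with the protease Lonp1 (1.31, SE 0.043), Afg3l2 (0.89, SE 0.043) and Hspa9 (0.36, SE 0.026) among the rises.

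Of 59 nuclear-encoded subunits of oxidative phosphorylation, 22 rose and 5 fell (camera adjusted p = 0.0735), with Uqcrq (log2 fold change 0.66), Ndufs3 (0.61) and Ndufa1 (0.42) showing the clearest rises. The list passed the threshold once CRE2 (adjusted p = 0.0274), CRE3 (0.0218) or wild-type library 3 (0.0382) was left out, but not with an estimated correlation (adjusted p = 0.862) or with the length and GC trend taken out (0.464), and with total counts alone its direction turned to lower (0.781). Over the other settings its rises numbered 4 to 25 and its falls 0 to 32. The 13 mitochondrially encoded subunits gave 3 rises and 4 falls (adjusted p = 0.697). ND1 (0.29) rose and ND6 (−0.35) fell, while ND2 (0.12) rose with TMM factors and had the opposite sign, −0.088, with total counts alone. With upper-quartile factors ND2 was not called in edgeR's test (0.030, adjusted p = 0.344). The rise of ND1 was lost on unfiltered log2(FPKM + 1) (adjusted p = 0.196). The rise called for the mitochondrial gene COX2, named after its value was seen, came with 70.0 ± 39.5 CPM in the knockout against 46.8 ± 3.34 CPM in the wild type, and CRE2 held 4092 of its counts against 1413 and 1377 in the other knockout libraries. Over the other settings this list gave 0 to 3 rises and 1 to 10 falls. Transcripts of these 13 genes took 1.93% ± 0.086 of the counts in the knockout and 2.24% ± 0.039 in the wild type. In the list for mitochondrial biogenesis and DNA maintenance, 5 of 17 members rose and 3 fell (adjusted p = 0.841; over the other settings 2 to 6 rises and 2 to 11 falls), with rises of Twnk (0.80), Top1mt (0.95) and Tfb2m (0.37), the last lost on unfiltered log2(FPKM + 1) (adjusted p = 0.107). In fatty acid oxidation and the tricarboxylic acid cycle, 5 of 32 members rose and 9 fell (adjusted p = 0.546; over the other settings 2 to 6 rises and 6 to 27 falls). Idh2 (−1.35) and Cpt1a (−0.85) fell and Ppard (0.83) rose.

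Targets of the integrated stress response were divided, with 13 of 26 members higher and 12 lower (camera adjusted p = 0.841; over the other settings 8 to 13 rises and 9 to 14 falls). Vldlr (log2 fold change 2.00, SE 0.035) and Stc2 (2.91, SE 0.066) rose, and Phgdh (−1.54, SE 0.052), an enzyme of serine synthesis, fell. Chaperones of the endoplasmic reticulum rose in 15 of 29 cases and fell in 3 (adjusted p = 0.0509). The chaperone Hspa5 rose 1.58-fold, from 1022 ± 12.4 to 1612 ± 22.1 CPM, and P4hb and Calr each rose 1.49-fold. This list passed the threshold once CRE2 (adjusted p = 0.0274) or CRE3 (0.0325) was left out, or with DESeq2's size factors (0.0454), but not with total counts alone (0.277) or an estimated correlation (adjusted p = 0.598), and over the other settings its rises numbered 10 to 16 and its falls 1 to 12. The NRF2 and antioxidant list held 14 rises and 8 falls among 26 members (adjusted p = 0.0858; over the other settings 11 to 14 rises and 3 to 12 falls). The mitochondrial superoxide dismutase Sod2 rose 5.57-fold, Sod3 rose 3.23-fold and Prdx5 rose 2.64-fold.

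Interferon-stimulated and cGAS-STING genes gave 12 rises and 16 falls among 32 members (camera adjusted p = 0.622). Zbp1 (log2 fold change 2.12) rose, and Ifit3 (−1.88) and Ifit3b (−2.22), near-identical copies with uncertain separate values, fell. Of 26 genes of apoptosis, p53 and senescence, 9 rose and 10 fell (adjusted p = 0.825; over the other settings 4 to 9 rises and 6 to 17 falls), with Cdkn1a (0.84) and Zmat3 (0.50) higher and Sesn1 (−1.18) lower. Autophagy and lysosome genes gave 10 rises and 11 falls among 30 members (adjusted p = 0.936; over the other settings 5 to 11 rises and 9 to 18 falls), with Ctsd (−0.52) and Ctsb (−0.37) lower and Atg9a (0.87) higher. Cholesterol and fatty acid synthesis gave 9 rises and 12 falls among 28 members (adjusted p = 0.939; over the other settings 7 to 10 rises and 6 to 18 falls), with Scd2 (1.10) and Scd1 (0.71) higher.

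Proliferation genes fell. Of 33 members, 30 fell, 1 rose and 2 did not pass the test, with a median log2 fold change of −2.37 (camera adjusted p = 1.58e-11, and adjusted p = 0.0298 with an estimated correlation). Mki67, a protein of dividing cells, fell 13.2-fold, from 81.0 ± 2.91 to 6.09 ± 1.25 CPM, the ribonucleotide reductase subunit Rrm2 fell 5.24-fold and the cyclin Ccna2 fell by 3.33 on the log2 scale. The member that rose was E2f1 (0.68), named after its value was seen. Macrophage markers fell over the same libraries (list median −4.05), and the immediate-early list had a median of 0.78.

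TGF-beta, BMP and SMAD signalling genes gave 12 rises and 11 falls among 27 members (camera adjusted p = 0.906). The BMP antagonist Grem1 (log2 fold change 1.54) rose and Tgfb2 (−1.33) fell. In WNT and hedgehog signalling, 5 of 28 members rose and 16 fell (adjusted p = 0.0757). The secreted WNT modulators Sfrp2 (−2.57) and Dkk3 (−0.95) fell, and Ptch1 (2.04), the hedgehog receptor, rose.

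**Figure D2:**
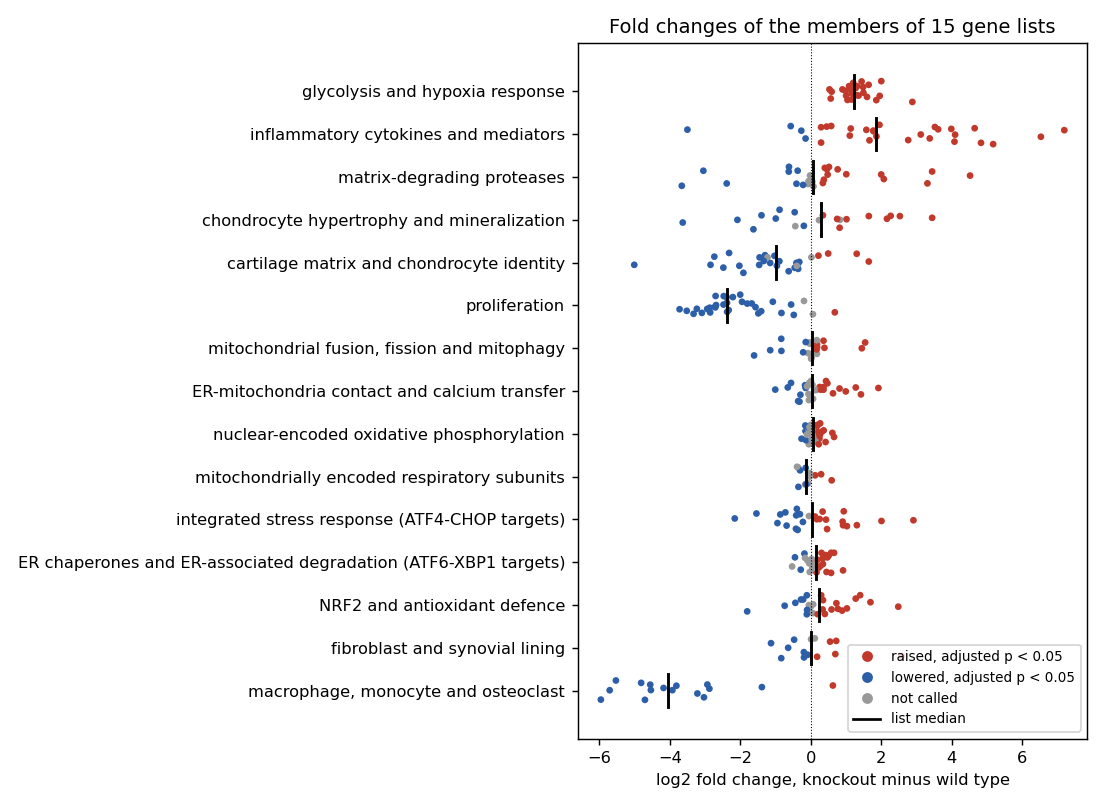
Log2 fold changes (knockout minus wild type) of the tested members of 15 gene lists, with 1 point per gene, red for rises and blue for falls at an adjusted p under 0.05, grey for genes not called, and a black line at each list median. The medians were 1.86 for inflammatory mediators, 1.23 for glycolysis and hypoxia, −0.998 for cartilage, −2.37 for proliferation and −4.05 for macrophage markers.

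Markers of macrophages, monocytes and osteoclasts fell, with 15 of 16 members lower and 1 higher and a median log2 fold change of −4.05 (camera adjusted p = 2.79e-09, and adjusted p = 0.0298 with an estimated correlation). The lysozyme Lyz2 fell from 1748 ± 24.9 to 229 ± 9.25 CPM (−2.94, SE 0.032). The member that rose was Acp5 (0.62), named after its value was seen. Fibroblast and synovial lining markers gave 6 rises and 7 falls among 15 members (adjusted p = 0.697; over the other settings 4 to 6 rises and 3 to 8 falls), and the proteoglycan Dcn rose 3.21-fold. Immediate-early and dissociation-response genes rose in 12 of 19 cases and fell in 5 (median 0.78, adjusted p = 0.0263, but adjusted p = 0.218 with an estimated correlation, and 0.0507 with a trend on gene length and GC content taken out), with Ier3 up 9.94-fold.

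The marker lists of other cell types did not pass the threshold in camera's main test with all 6 libraries. With a CPM above 1 in 3 libraries the osteoblast list passed it (adjusted p = 0.0341). Neutrophil and lymphocyte markers rose in 2 of 3 tested cases, with Camp at 3.48 ± 0.442 CPM in the knockout and 0.179 ± 0.034 CPM in the wild type. Endothelial markers gave 2 rises and 2 falls among 8 (over the other settings 1 to 2 rises and 0 to 2 falls), with Plvap at a log2 fold change of 1.62. Pericyte and smooth muscle markers gave 2 rises and 4 falls among 10 (over the other settings 0 to 3 rises and 3 to 6 falls), and Acta2 fell (−1.44). Skeletal muscle markers gave 5 rises among 14 (over the other settings 1 to 6), with Des up (1.38), and this list passed the threshold once CRE2 was left out (adjusted p = 0.0274) but not without any other library. Erythroid markers gave 1 rise among 3 (over the other settings 1 to 3). Adipocyte markers gave 1 rise and 1 fall among 6 (over the other settings 1 to 2 rises and 1 to 3 falls), with Fabp4 up (1.73). Neural and Schwann markers gave 3 rises and 2 falls among 8 (over the other settings 2 to 3 rises and 1 to 3 falls), with Ncam1 up (2.21). Keratinocyte markers gave 2 falls among 5, including Perp (−2.37). Among 5 sex-linked genes, Kdm5d (−0.65) and Xist (−0.40) fell and Uty (0.23) rose, whereas Eif2s3y (−0.08) and Ddx3y (−0.10) did not pass the test with TMM factors. With total counts alone both were called lower, Eif2s3y at −0.291 (adjusted p = 0.00407) and Ddx3y at −0.306 (0.0106), as they were on log2(FPKM + 1) and log2(FPKM + 0.1). The rise of Uty was lost without CRE3 (adjusted p = 0.0670) or wild-type library 3 (0.0840), and with upper-quartile factors (0.144) or total counts alone (0.804), and in the 3 FPKM settings. Every library held both Xist (557 to 890 CPM) and Ddx3y of the Y chromosome (30.9 to 44.4 CPM), as a pool of male and female cells would. Whether the libraries of a group were drawn from the same pool is not given by the labels.

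Camera, which asks whether a list ranks apart from other genes, called 6 of 36 lists, 3 upward and 3 downward, and 3 of them held with an estimated correlation. Other splits of the 6 libraries into groups of 3 gave up to 8 such calls, but each of them has knockout and wild-type libraries on both sides. They still carry part of the real contrast, so this number does not measure chance. Adjusted over the list alone, the counts were the same as over all genes tested in 28 lists and differed in 8. Besides cartilage, these were the contacts of endoplasmic reticulum and mitochondria (13 rises, 9 falls), nuclear-encoded subunits (20 and 5), mitochondrially encoded subunits (2 and 4), fatty acid oxidation (4 and 9), lipid synthesis (10 and 13), pericyte (2 and 5) and skeletal muscle markers (4 and 0). In 6 lists the median, the mean and the direction of the test did not share a sign: mitochondrial fusion and fission, mitochondrial biogenesis, cholesterol synthesis, TGF-beta signalling, endothelial and keratinocyte.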

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

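The settings using total counts alone, without the 20 most abundant genes, with the length and GC trend taken out, and with a block on the number in the column names were chosen after seeing the data. The planned block took its numbers from the sample titles, to which the knockout columns are not tied by name, so it was run on the number at the end of each column name instead. This block gave 9094 changed genes, 4437 raised and 4657 lowered, and changed no call of a named gene or list. Deviations from the group means correlated at −0.086, 0.055 and −0.095 for columns 1, 2 and 3, and not every library correlated best with its own number. With 3 libraries per group, these values cannot tell whether columns with the same number share a litter, day or batch. Against 9430 changed genes, a test against a 1.2-fold change called 5856, with 2724 raised and 3132 lowered, since it asks for a larger effect. Raised genes numbered 4607 in the reported test and 2354 on log2(FPKM + 1), 2345 on log2(FPKM + 0.1), 2706 on unfiltered log2(FPKM + 1) and 2789 with total counts alone, and lowered genes rose from 4823 to 7328 in the unfiltered FPKM setting and 7627 with total counts alone. FPKM also divides by the column total, without TMM factors. Changes of at least 2-fold numbered 2965, and 1196, 1589 and 1293 in the 3 FPKM settings, in that order; the cause was not tested. Camera called 3 lists with an estimated correlation instead of 6, fry called 26 for movement one way and 35 for change in either direction, and fry does not compare a list with other genes.

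With an estimated correlation, camera's calls for glycolysis and hypoxia (adjusted p = 0.212), cartilage (0.0657) and the immediate-early list (0.218) were lost, and the last was also lost with the length and GC trend taken out (0.0507). Camera gained a call for chaperones of the endoplasmic reticulum (ER) with DESeq2's size factors (0.0454) and for the osteoblast list with a CPM above 1 in 3 libraries (0.0341). Leaving out 1 library at a time gave adjusted p from 0.0274 to 0.0767 for ER chaperones, from 0.0218 to 0.213 for nuclear-encoded respiratory subunits and from 0.0274 to 0.730 for skeletal muscle. Fry for movement one way added the lists for hypertrophy (adjusted p = 1.77e-06), osteoblast (2.04e-06), proteases (7.13e-06), NRF2 (1.38e-05), WNT (1.38e-05), organelle contacts (2.79e-05), mitochondrial fusion and fission (3.88e-05), fibroblast (4.79e-05), protease inhibitors (6.38e-05), pericyte (8.93e-05), neutrophil (9.91e-05), ER chaperones (0.000125), mitochondrial chaperones (0.000156), neural (0.000414), interferon (0.000775), integrated stress response (0.00235), keratinocyte (0.0133), fatty acid oxidation (0.0148) and nuclear-encoded respiratory subunits (0.0346). The list for cholesterol and fatty acid synthesis had the opposite direction in fry (adjusted p = 0.00756); the cause was not tested. Fry for change in either direction added hypertrophy (1.36e-09), proteases (1.95e-09), TGF-beta (5.74e-08), WNT (6.13e-08), mitochondrial fusion and fission (6.31e-08), organelle contacts (1.05e-07), protease inhibitors and fibroblast (1.50e-07 each), interferon (1.83e-07), NRF2 (2.48e-07), cholesterol and fatty acid synthesis (3.15e-07), fatty acid oxidation (3.32e-07), osteoblast (4.35e-07), integrated stress response and pericyte (4.45e-07 each), ER chaperones (1.49e-06), autophagy (1.52e-06), apoptosis (1.55e-06), neural (3.01e-06), mitochondrial chaperones (4.14e-06), endothelial (8.73e-06), adipocyte and mitochondrially encoded subunits (1.20e-05 each), nuclear-encoded respiratory subunits (4.46e-05), keratinocyte (5.57e-05), mitochondrial biogenesis (6.64e-05), sex-linked genes (0.00234), neutrophil (0.00385) and skeletal muscle (0.0105).

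ND2 changed sign on log2(FPKM + 1), log2(FPKM + 0.1) and unfiltered log2(FPKM + 1), and with total counts alone (−0.088 in each, against 0.12). With total counts alone the median of all genes moved by −0.209, and ND2 moved by as much. The FPKM settings also lack TMM factors, but they change the test and the transform as well. Leaving out each library in turn gave 8660 to 9547 changed genes, and DESeq2 gave 8904. Mfn2 stayed lower and past the threshold in all 20 settings. Over the other 103 named genes, 2025 values kept direction and side of the threshold, 13 lost the call, 6 gained one and 4 reversed, all of these 4 for ND2. In lists, 4 calls were lost and 56 gained, and 19 list results changed direction without a call on either side. In simulated counts with the depths and replicate number of these libraries but few changed genes, the test recovered 50% of genes changed by the smallest fold simulated.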

Other observations

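The gene lists in the first 2 paragraphs and the tests of library scaling, of fewer macrophages, of neutrophils, of the most abundant genes, of length and GC content and of dilution by other cells were chosen after the results were seen. Leaving out the 20 most abundant genes, the test first written for them, gave 9422 changed genes against 9430 and moved too little to decide, so their share of the counts was used instead. Imprinted genes that regulate growth fell in 13 of 16 tested cases and rose in 3, with a median log2 fold change of −1.25 (camera adjusted p = 0.000133, and adjusted p = 0.0416 with an estimated correlation, over 5 added lists). Meg3 fell from 359 ± 3.31 to 106 ± 2.66 CPM (SD, n = 3), Peg3 fell by 1.48 on the log2 scale, and H19 and Igf2, which share an imprinted domain, stood at log2 fold changes of −0.92 and −0.56. Over the same libraries macrophage markers fell (list median −4.05) and the immediate-early and dissociation-response list had a median of 0.78 (adjusted p = 0.0263, but adjusted p = 0.218 with an estimated correlation). Beside these same 2 marker lists, metallothioneins and zinc importers rose in 8 of 12 cases and fell in 0 in edgeR's test (adjusted p = 0.000211, and adjusted p = 0.0416 with an estimated correlation). Mt1 rose 12.4-fold, from 268 ± 8.85 to 3321 ± 90.9 CPM, Mt2 rose 12.8-fold, and the zinc importers Slc39a14 and Slc39a8 rose 5.65-fold and 5.10-fold.

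Over the same libraries, macrophage markers had a median of −4.05 and the immediate-early list one of 0.78. MHC class I genes rose in 11 of 14 cases and fell in 2 (camera adjusted p = 0.000211, but adjusted p = 0.0886 with an estimated correlation). Their log2 fold changes ran from −2.90 to 7.05, so they did not move alike. H2-K1 rose 2.35-fold while H2-D1 had a log2 fold change of −0.12. These genes resemble one another and their separate counts are uncertain. Of 6 class II genes 2 rose (adjusted p = 0.166). H2-Ab1 stood at 217 ± 9.23 CPM in the knockout and 36.3 ± 2.41 CPM in the wild type, while its partner H2-Aa was at 0.624 ± 0.245 and 0.250 ± 0.057 CPM. Cytosolic ribosomal protein genes fell in 41 of 58 cases and rose in 2, with a median of −0.16 (adjusted p = 0.000133, but adjusted p = 0.405 with an estimated correlation), a size below the shift of 0.209 that total counts alone gave the median of all genes. The joint-development factor Gdf5 rose 7.42-fold beside the falls of Col2a1 and Acan.

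The fall of macrophage markers was larger than the shifts given by the 3 other scalings tried. The largest shift of the median of all genes between them and TMM was 0.209 on the log2 scale, against a list median of −4.05, which argues against library scaling as the source. A lower share of macrophages in the knockout samples is a candidate explanation that stays open: the members fell by different amounts (SD of the log2 fold changes 1.68), but 5 of 16 members were over 10 CPM in the knockout, where other cells can set a floor. None of the list's members is on another list, and the abundant Lyz2 was at 229 CPM in the knockout. Whether Mfn2 loss alters macrophage number or the isolation of the cells differed between groups was not tested.

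The rise of inflammatory mediators, with a list median of 1.86, is set against 2 technical sources. The larger share of the 20 most abundant genes in the knockout would move all other genes by −0.080 on the log2 scale under total counts. A larger share can only lower the other genes, so it cannot give a rise. The fitted length and GC trend was at most 0.088 in size for any member, so taking it out could change little. The median was then 1.86 and the list kept its call. The direction of the first and the size of the second argue against both as the whole cause. A large share of neutrophils in the knockout samples is argued against by S100a8, at 2.51 CPM in the knockout, and S100a9, which was lower still. Going the other way, Camp rose from 0.179 to 3.48 CPM, and 2 of 3 tested members of the neutrophil and lymphocyte list rose. A small share of neutrophils therefore stays open. A response of the chondrocytes to Mfn2 loss, a response to the lower macrophage signal, and a difference in culture or handling stay open as hypotheses, untested here.

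The fall of cartilage genes had a list median of −0.998. The same shift of −0.080 is far smaller. The fitted length and GC trend was at most 0.168 in size for any member, so taking it out could change little. The median was then −0.967 and the list kept its call at the preset correlation. These sizes argue against both as the whole cause. With an estimated correlation camera did not call the list even before the trend was taken out (adjusted p = 0.0657). For dilution of chondrocytes by other cells, the medians of the marker lists with at least 8 tested members spread over 4.36 on the log2 scale. That spread speaks only against a like rise of every one of those types. Its lower end is the macrophage list (−4.05), and other cells need not rise alike, so it does not decide on dilution. The list members ran from −5.01 to 1.64 on the log2 scale (SD 1.34), so they did not fall by 1 common factor. Other cells may express some members, so this spread does not decide either. Dilution by 1 or more cell types stays open, as does an effect of Mfn2 loss on chondrocyte identity. The labels name the genotype but not such an effect, which was not tested separately.

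The 10 possible splits of the 6 libraries are too few for a share under 0.05. The real split gave 9430 changed genes, 4607 raised, 4823 lowered and 2965 changed at least 2-fold, and it was 1 of 10 splits to give as many, for each of these counts. The highest of the other splits gave 0 genes in edgeR's test for each count, with up to 117 at an unadjusted p under 0.05. For lists, 6 of the 10 splits gave as many calls as the real one, 6, and the highest of the others gave 8. Every other split has knockout and wild-type libraries on both sides. The real difference then widens the spread within each side in the gene test, and can still rank genes in the list test. So neither the 0 genes nor the list calls of the other splits measure chance.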
